A study of Homo sapiens with 6 samples.

How the data were processed

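RNA was precipitated from OCI-AML2 cells, a human acute myeloid leukaemia (AML) line, with J2, a monoclonal antibody that binds double-stranded RNA, and was sequenced after a directional library preparation, per the labels' protocols. The cells carried a short hairpin RNA against PNPT1 in 3 libraries and against SUPV3L1 (SUV3) in 3 libraries, and per the series' design text each group holds 3 biological replicates. No library of control cells and no library of RNA before precipitation was analysed here, so every comparison is SUPV3L1 knockdown against PNPT1 knockdown. Replicates were numbered in accession order, and the numbers pair no libraries. What the numbers in the sample titles stand for is not given in the sources used here, so whether the libraries of a group share a hairpin is unknown, and the spread within a group could include differences between hairpins.

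The deposited count tables hold whole-number read counts for 60675 Ensembl gene identifiers in each library, followed by 5 summary lines of the kind HTSeq writes. Per the submitters' processing notes, the tools were HISAT2 2.2.1, SAMtools 1.14, StringTie 2.1.4 and HTSeq, with the GRCh38 genome. The HTSeq version, its strand setting and the annotation release are not given in the sources used here. Without the strand setting, it is not known whether reads from the strand opposite to a gene were counted for it, which matters for mitochondrial genes, MT-ND6 included, because both mitochondrial strands are transcribed. The deposited FPKM table gives fragments scaled to gene length and to library depth for the same genes, and which of the named tools made it is not given in the sources used here. Its columns were matched to libraries by their titles.

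The summary lines were kept out of library sizes and tests. Alignments that were not unique made up 65.7% to 80.1% of the entries, with the highest share in PNPT1 knockdown replicate 3, and 7.06% to 16.0% of entries were assigned to a gene. These entries are alignments, so a read with several positions can be entered more than once. Such reads give no counts, which can lower genes with near-identical copies. RN7SL1 had 0 counts in the 6 libraries and 52733 to 113851 FPKM, and 11 genes reached a mean of 1000 FPKM or more with fewer than 10 counts. RN7SL1, RMRP and RPPH1 each have more than 1 identifier, so overlapping annotation is another possible reason, and the cause was not tested. Values for histone, ribosomal protein, heat shock and mitochondrial genes, which have close paralogs, pseudogenes or nuclear copies, are uncertain where reads align to more than 1 place.

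Assigned counts ranged from 5852090 to 11361371 per library. Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with TMM scaling and the default expression filter (a minimum count of 10, scaled to library size, and a total of 15), which left 13275 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are CPM (counts scaled to library size) after TMM scaling unless stated otherwise, and standard errors of log2 fold changes were derived from the fold change and its F statistic. Shares of counts were compared by a two-sided exact permutation test of the difference of means, in which 3 libraries against 3 cannot give a p below 0.1. Binomial 95% intervals of shares (Wilson) cover counting error only and were at most ±0.0991 percentage points.

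Gene lists, 23 in all, were written from general knowledge before the data were examined, as were the tests of genes, of lists, of the mitochondrial share and of the MT-ND6 share, the rule for naming genes and most alternatives. The other 8 of the 10 share and ratio measures were chosen after the data were seen. A list with 5 or more measured members was tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry (limma 3.58.1). The rule named SUPV3L1 and PNPT1, the mitochondrial rRNAs and mRNAs, the 10 largest changes in each direction among genes past the threshold with a mean of 50 counts or more and no overlap between groups or, where none passed, the 5 genes with the smallest p in each direction, the 3 members with the smallest p of each list described, and the 5 genes with the highest mean CPM. Genes named outside this rule are stated as chosen after their values were seen. One gene that the rule named is not reported here. One group of 42 genes, named after clones beginning AL353644, AL592188, FP236383 or FP671120 and called clone-named genes below, was also defined after the data were seen, because it took a large part of the counts. GENCODE 29 places some other genes named after FP236383 and FP671120 on chromosome 21 within the ribosomal RNA genes, and whether the counts of the group come from cytosolic ribosomal RNA was not tested.

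Gene positions and types come from GENCODE 29 on GRCh38, which holds 57055 of the 60675 identifiers. Symbols come from the deposited FPKM table, and current symbols were matched for 56558 identifiers. The alternatives were DESeq2 1.42.0, other scalings, other filters, limma on the deposited FPKM values on the log2(FPKM + 1) and log2(FPKM + 0.1) scales with a filter of 1 FPKM in 3 libraries, and leaving out each library in turn.

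The test was checked on simulated counts for the 13275 genes with the means, dispersions and library sizes of these libraries. It recovered 1 of 67 genes changed 2-fold, 39 of 67 changed 4-fold and 57 of 66 changed 8-fold, with 4 false calls. Genes were drawn independently of each other, so the simulation held no variation shared between genes and no library that stands apart. Its recovery rates may therefore be higher than those in the real libraries. No pair of libraries was alike within sampling noise: the chi-square per degree of freedom over genes was 38.7 or higher for every pair. Figures were drawn with matplotlib 3.10.9.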

Results

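The libraries describe RNA bound by the J2 antibody in OCI-AML2 leukaemia cells in which 1 of 2 mitochondrial RNA decay factors had been knocked down. PNPT1 encodes polynucleotide phosphorylase, a 3′ to 5′ exoribonuclease, and SUPV3L1 encodes the RNA helicase that works with it in the mitochondrial matrix. The 3 PNPT1 knockdown libraries had 8352570, 10464630 and 5852090 counts assigned to genes in replicates 1, 2 and 3, and the 3 SUPV3L1 knockdown libraries had 11361371, 10008797 and 9378264. At least 1 count was found for 20765, 21572 and 16620 genes in the PNPT1 knockdown libraries and for 22393, 21049 and 22206 in the SUPV3L1 knockdown libraries. PNPT1 knockdown replicate 3 had the fewest counts and genes, and its correlations with the other libraries across genes were the lowest (Pearson's r of log2 CPM 0.838 to 0.888). The highest correlation was between groups, at r = 0.970 for PNPT1 knockdown replicate 2 and SUPV3L1 knockdown replicate 2 (genes are not independent replicates).

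The targeted genes were examined first. PNPT1 RNA (ENSG00000138035, chromosome 2, 55634265 to 55693910, minus strand) was at 7.66, 18.9 and 17.1 CPM in the PNPT1 knockdown libraries and at 36.3, 27.6 and 21.4 CPM in the SUPV3L1 knockdown libraries. Its log2 fold change, SUPV3L1 minus PNPT1 knockdown, was 0.97 ± 0.41 (SE, n = 3 per group). SUPV3L1 RNA (ENSG00000156502, chromosome 10, 69180232 to 69209099, plus strand) was at 11.5, 18.2 and 25.8 CPM in the PNPT1 knockdown libraries and at 12.2, 12.3 and 9.42 CPM in the SUPV3L1 knockdown libraries, a log2 fold change of -0.70 ± 0.39 (SE, n = 3 per group). Each targeted RNA thus had its lower mean in its own knockdown, without overlap for PNPT1 and with overlap for SUPV3L1. Neither passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (adjusted p = 0.898 for both). The log2 fold change of SUPV3L1 was -0.40 without PNPT1 knockdown replicate 3. These values are of precipitated RNA and do not measure total mRNA or protein.

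The study's title places mitochondrial RNA degradation in AML, and the first comparison asked what share of the counts assigned to genes was mitochondrial. Alignments that were not unique give no counts, so these shares do not measure the mitochondrial part of all precipitated RNA. Mitochondrially encoded genes took 36.7% ± 4.60 (SD, n = 3) of counts in SUPV3L1 knockdown and 19.8% ± 7.81 (SD, n = 3) in PNPT1 knockdown. The ribosomal RNAs MT-RNR1 (12S) and MT-RNR2 (16S) made up most of this: 30.0% ± 2.13 (SD, n = 3) against 15.2% ± 5.53 (SD, n = 3), 1.98-fold by the means. The 13 mitochondrial mRNAs took 6.65% ± 2.47 (SD, n = 3) against 4.64% ± 2.42 (SD, n = 3), with overlapping groups. All 3 SUPV3L1 knockdown libraries lay above all 3 PNPT1 knockdown libraries for the mitochondrial share and the rRNA share. The exact permutation test gave p = 0.1 for both, the smallest that 3 against 3 can give (Benjamini-Hochberg adjusted p = 0.333 over 10 measures), and p = 0.6 for the mRNAs (adjusted p = 0.857 by the same method). PNPT1 knockdown replicate 3, the library with the fewest genes detected, had the lowest mitochondrial share, 11.3%. The difference lay between 12.6 and 20.2 percentage points when each library was left out in turn. As a share of summed FPKM, mitochondrially encoded genes took 17.7% ± 2.71 in SUPV3L1 knockdown and 7.52% ± 4.39 in PNPT1 knockdown (SD, n = 3).

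The 42 clone-named genes went the other way, with a mean of 25.2% of counts in PNPT1 knockdown and 12.1% in SUPV3L1 knockdown (n = 3) (exact permutation p = 0.1, Benjamini-Hochberg adjusted p = 0.333). The PNPT1 knockdown libraries had 15.9%, 22.1% and 37.7%, and the SUPV3L1 knockdown libraries 10.9%, 14.6% and 10.9%. Shares are parts of one total, so the higher mitochondrial share by itself lowers that of the clone-named group. It was not tested whether the group's share still separates the knockdowns with mitochondrial counts left out of the total. AL353644.10, a member of this group, had the highest mean CPM over the 6 libraries, at 260257 ± 190093 CPM in PNPT1 knockdown and 103656 ± 17703 CPM in SUPV3L1 knockdown (SD, n = 3), where MT-RNR1 and MT-RNR2 lay above it in each library. Its log2 fold change was -1.33, and -0.56 without PNPT1 knockdown replicate 3, in which it was at 476424 CPM. The TMM factor of that library, 0.669, raises CPM above the plain share of counts. These CPM therefore cannot be set against the percentages of counts. The identifiers of the group have no position in the annotation used here, and whether their counts come from cytosolic ribosomal RNA was not tested. RN7SK, the RNA of the 7SK ribonucleoprotein, took 4.21% ± 1.09 of counts in PNPT1 knockdown and 2.96% ± 0.774 in SUPV3L1 knockdown, and the nuclear RNA MALAT1 took 1.31% ± 0.311 and 1.21% ± 0.409 (SD, n = 3).

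**Figure D1:**
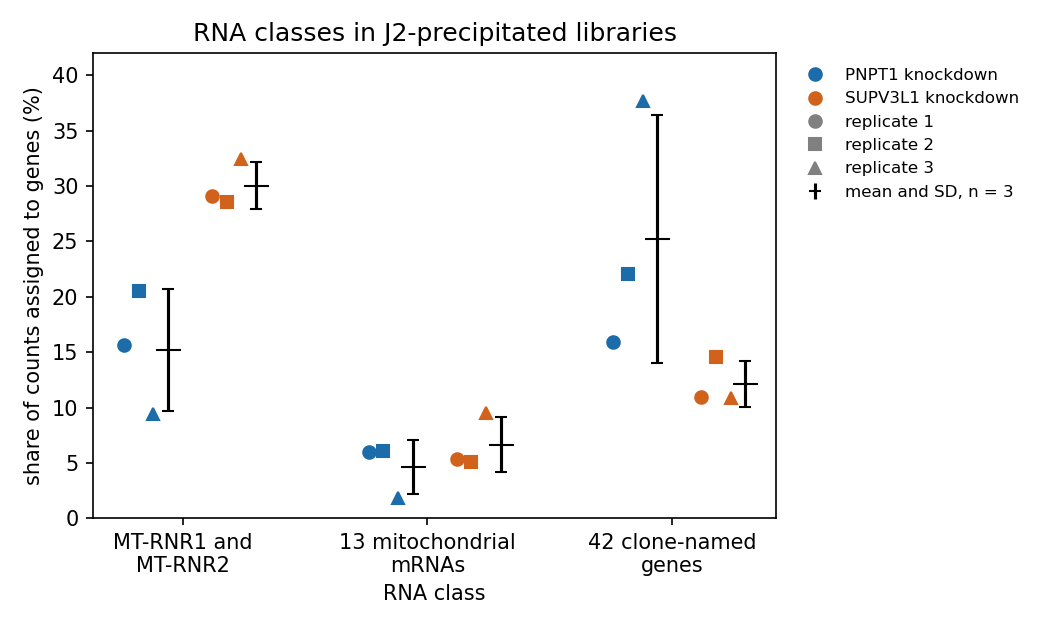
Share of the counts assigned to genes, in percent, for the mitochondrial rRNAs, the 13 mitochondrial mRNAs and the 42 clone-named genes; each symbol is 1 library, and black bars give the mean and SD of 3 libraries. The rRNA share was 28.5% to 32.5% in the SUPV3L1 knockdown libraries and 9.44% to 20.5% in the PNPT1 knockdown libraries.

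Among the mitochondrial mRNAs, MT-CO2 and MT-ATP6, which encode subunits of cytochrome c oxidase and ATP synthase, had the smallest p-values. MT-CO2 was at 6504 ± 1313 CPM in SUPV3L1 knockdown and 2991 ± 1329 CPM in PNPT1 knockdown, and MT-ATP6 at 4261 ± 649 and 2346 ± 624 CPM (SD, n = 3). MT-ND4L, a complex I subunit mRNA, was at 1601 ± 407 and 1094 ± 295 CPM (SD, n = 3). The log2 fold changes of the 13 mRNAs ranged from 0.25 for MT-ATP8 to 1.12 for MT-CO2, all above 0 (MT-ATP8 was at -0.0599 without SUPV3L1 knockdown replicate 2), and those of MT-RNR1 and MT-RNR2 were 0.98 ± 0.85 and 0.87 ± 0.84 (SE). None passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes, and none adjusted over the list alone (smallest adjusted p = 0.612). As a list, the mRNAs passed camera with a preset correlation (median log2 fold change 0.52, Benjamini-Hochberg adjusted p = 0.00589 over 18 lists) and not with an estimated one (adjusted p = 0.689). The camera call was also lost without PNPT1 knockdown replicate 3 (median 0.20) or SUPV3L1 knockdown replicate 3 (median 0.31). Without the latter, MT-ND5, MT-ND3, MT-CYB, MT-CO3 and MT-ND4 had log2 fold changes of -0.89, -0.72, -0.20, -0.18 and -0.13.

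MT-ND6 is the mRNA read from the light strand, opposite to the other 12, and its share of mitochondrial mRNA counts was compared because the libraries hold RNA selected as double-stranded. The share was 4.12%, 8.66% and 2.84% in the PNPT1 knockdown libraries and 1.32%, 9.82% and 5.20% in the SUPV3L1 knockdown libraries. The means, 5.21% ± 3.06 and 5.44% ± 4.25 (SD, n = 3), differed by less than the spread between replicates (exact permutation p = 1, Benjamini-Hochberg adjusted p = 1). Without SUPV3L1 knockdown replicate 2 the difference was -1.95 percentage points, and without SUPV3L1 knockdown replicate 1 it was 2.30. The 7 light-strand genes measured had a median log2 fold change of -0.26, while camera's statistic pointed upward (Benjamini-Hochberg adjusted p = 0.770), and the median was 1.34 without PNPT1 knockdown replicate 2, where the list passed camera (Benjamini-Hochberg adjusted p = 0.0359), and -1.26 without SUPV3L1 knockdown replicate 3. MT-TT and MT-TI, the only heavy-strand tRNA genes left by the filter, were at 6.19 ± 3.59 and 13.7 ± 3.64 CPM in SUPV3L1 knockdown and at 1.52 ± 1.32 and 4.78 ± 4.34 CPM in PNPT1 knockdown (SD, n = 3). PNPT1 knockdown replicate 3 had 0 counts of both. Without that library the log2 fold change of MT-TI was 0.93, against 1.45 with all. Neither gene passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.898 for both).

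Across all genes, no single gene separated the knockdowns after correction in the main test. Of 13275 genes, 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.898). At an unadjusted p under 0.05 there were 543 genes, 226 with the higher and 317 with the lower level in SUPV3L1 knockdown, where chance alone gives 663.75. DESeq2 called 18 genes, 13 higher and 5 lower, and edgeR without the expression filter called 187. The groups did not overlap for 1136 genes, 8.56% of those tested, where chance gives 10%.

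The genes with the smallest p-values on the higher side were MGAM2, PTAFR, OR52K3P, KIAA0513 and LYZ. DESeq2 called each of these and, of the genes named on the lower side below, all but AC245100.1. LYZ encodes lysozyme, an enzyme of monocytes and granulocytes, and PTAFR the receptor for platelet-activating factor. LYZ was at 36.6, 180 and 144 CPM in the PNPT1 knockdown libraries and at 1493, 344 and 1331 CPM in the SUPV3L1 knockdown libraries, a log2 fold change of 3.14 ± 0.70 (SE). PTAFR was at 1.81 ± 2.09 against 22.8 ± 6.53 CPM (SD, n = 3). MGAM2, a maltase-glucoamylase relative, was at 7.07, 9.26 and 3.07 CPM in PNPT1 knockdown and at 76.0, 22.4 and 60.5 CPM in SUPV3L1 knockdown. The fitted log2 fold changes of KIAA0513 and the pseudogene OR52K3P were 4.63 ± 1.03 and 3.61 ± 0.78 (SE), at mean levels under 5 CPM. On the lower side were FP236383.4, CH507-513H4.4, AL353644.1, AC245100.1 and FP236383.12, with log2 fold changes of -3.05, -3.17, -3.47, -3.33 and -3.01. AL353644.1 and AC245100.1 were near the floor in SUPV3L1 knockdown, at means of 0.594 and 0.190 CPM, so their fold changes are uncertain. CH507-513H4.4 lies on chromosome 21 at 8393419 to 8394341 (minus strand), inside the span of the ribosomal RNA genes RNA45SN3 and RNA18SN3, and its log2 fold change was -2.03 without PNPT1 knockdown replicate 1. FP236383.4 was at 515, 1397 and 3204 CPM in PNPT1 knockdown and at 285, 215 and 118 CPM in SUPV3L1 knockdown. On the deposited FPKM values (log2 of FPKM + 0.1) the log2 fold changes of FP236383.4, CH507-513H4.4, AL353644.1 and FP236383.12 were -1.37, -0.68, -0.84 and -1.10.

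The title names differentiation, stem cell function and immune-mediated killing, and gene lists for these were compared next. The levels are again of precipitated RNA. Without libraries of RNA before precipitation, a difference in expression cannot be told from one in precipitation. Mature myeloid markers had the highest median of the 18 lists tested: of 21 measured, 18 had a log2 fold change above 0, with a median of 1.52. No member passed edgeR's quasi-likelihood test over all genes, and 7 passed adjusted over the list alone, all higher in SUPV3L1 knockdown (LYZ, MS4A6A, VCAN, CSF1R, S100A9, S100A12 and S100A8, the last 4 named after their values were seen). DESeq2 called LYZ over all genes (Benjamini-Hochberg adjusted p = 0.00170). MS4A6A, a monocyte and macrophage membrane protein, was at 2.14 ± 1.29 CPM in PNPT1 knockdown and 9.92 ± 4.76 CPM in SUPV3L1 knockdown, and VCAN, a proteoglycan of monocytes, at 0.523 ± 0.462 and 11.9 ± 16.5 CPM (SD, n = 3). The list passed camera (Benjamini-Hochberg adjusted p = 1.75e-08) and not with an estimated correlation (adjusted p = 0.620). Without SUPV3L1 knockdown replicate 1, in which VCAN was at 30.9 CPM against 3.49 and 1.30 in the other replicates, the list's median was 0.51 and the log2 fold change of VCAN 2.00. That median was no longer the highest, with the mitochondrial mRNAs at 0.65 and the interferon-stimulated genes at 0.52. The list's mean log2 CPM was 3.64, 3.40 and 2.76 in the PNPT1 knockdown libraries and 5.62, 3.68 and 4.42 in the SUPV3L1 knockdown libraries. With the strict filter of 50 counts in every library of a group the median was 0.63.

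Stem and progenitor genes had a median log2 fold change of -0.49, with 12 of 17 members below 0 and none past the threshold, over all genes or adjusted over the list alone. SOCS2, a feedback inhibitor of cytokine signalling, was at 73.6 ± 48.1 CPM in PNPT1 knockdown and 24.1 ± 4.56 CPM in SUPV3L1 knockdown, and MEIS1, a homeobox factor of leukaemic self-renewal, at 123 ± 86.3 and 45.9 ± 3.50 CPM (SD, n = 3). DPYSL3 had a log2 fold change of -1.69 ± 0.79 (SE), and of -0.29 without PNPT1 knockdown replicate 1, in which it was at 12.2 CPM. Without PNPT1 knockdown replicate 3 those of SOCS2 and MEIS1 were -0.95 and -0.71. Camera gave a Benjamini-Hochberg adjusted p of 0.00950 and, with an estimated correlation, an adjusted p of 0.620. The call was lost without any 1 of 4 libraries: PNPT1 knockdown replicates 2 and 3 (medians -0.12 and -0.12) and SUPV3L1 knockdown replicates 1 and 3 (medians -0.12 and -0.41). With the strict filter the median was -0.13. The list's mean log2 CPM in SUPV3L1 knockdown replicate 2, 4.98, lay above PNPT1 knockdown replicates 1 and 2 (4.68 and 4.75).

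Interferon-stimulated genes had 35 of 42 members above 0 and a median log2 fold change of 0.60, with none past the threshold, over all genes or adjusted over the list alone. IFI16, a nucleic acid sensor, was at 2.74 ± 1.55 CPM in PNPT1 knockdown and 18.1 ± 18.2 CPM in SUPV3L1 knockdown (SD, n = 3). OAS2 and OAS3, oligoadenylate synthetases activated by double-stranded RNA, were at 7.33 ± 0.840 and 1.11 ± 1.03 CPM in PNPT1 knockdown and at 28.4 ± 21.4 and 8.27 ± 7.82 CPM in SUPV3L1 knockdown (SD, n = 3). OAS2 in SUPV3L1 knockdown replicate 2 was at 6.98 CPM, within the PNPT1 knockdown range. The mean log2 CPM of the list in that library, 2.79, lay below PNPT1 knockdown replicates 1 and 2 (2.84 and 2.89; replicate 3 at 2.39), so the difference rests on SUPV3L1 knockdown replicates 1 and 3 (3.83 and 3.85). Without SUPV3L1 knockdown replicate 1 the log2 fold changes of IFI16 and OAS3 were 1.43 and 1.70, against 2.66 and 2.82 with all libraries, and that of OAS2 was 1.28 without SUPV3L1 knockdown replicate 3, against 1.96. The list passed camera (Benjamini-Hochberg adjusted p = 1.09e-08) and not with an estimated correlation (adjusted p = 0.620), and its median stayed between 0.52 and 0.89 without each library. Sensors and effectors of double-stranded RNA, among them OAS2, OAS3 and OASL, had a median of 0.03, 12 of 23 above 0, and did not pass camera (Benjamini-Hochberg adjusted p = 0.246). Their median was -0.0281 without PNPT1 knockdown replicate 2 and 0.27 without PNPT1 knockdown replicate 1. The list passed camera upward without SUPV3L1 knockdown replicate 2 (median 0.0465, Benjamini-Hochberg adjusted p = 0.00187).

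Genes of immune recognition had a median log2 fold change of -0.21, 16 of 25 below 0, and did not pass camera (Benjamini-Hochberg adjusted p = 0.443). NCR3LG1, a ligand of the natural killer cell receptor NKp30, was at 52.8, 77.1 and 27.9 CPM in PNPT1 knockdown and at 97.0, 116 and 116 CPM in SUPV3L1 knockdown. CD47, a signal against phagocytosis, was at 154 ± 51.5 CPM in PNPT1 knockdown and 85.4 ± 23.6 CPM in SUPV3L1 knockdown, and C10orf54, the checkpoint protein VISTA, at 11.3 ± 7.34 and 22.2 ± 9.14 CPM (SD, n = 3). None of the 3 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.898 for each). Without PNPT1 knockdown replicate 3 the list's median was 0.0206, and without SUPV3L1 knockdown replicate 1 it was -0.54.

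**Figure D2:**
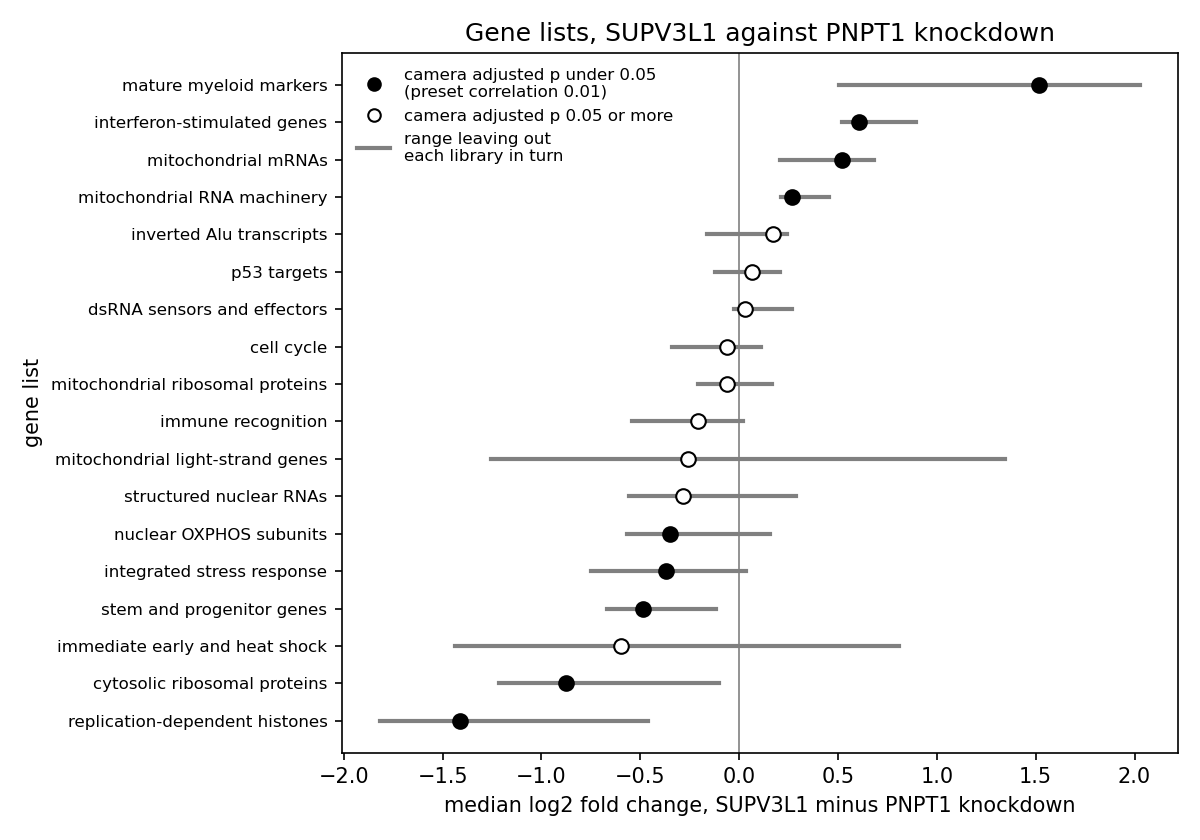
Median log2 fold change (SUPV3L1 minus PNPT1 knockdown) of each of the 18 lists tested; filled points passed camera with a preset correlation of 0.01, and grey lines span the medians with each library left out in turn. Mature myeloid markers lie highest at 1.52 and replication-dependent histones lowest at -1.41.

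The list of mitochondrial RNA machinery, which also holds nuclear genes of mitochondrial DNA maintenance, had 28 of 38 members above 0 and a median log2 fold change of 0.27. C10orf2, the mitochondrial DNA helicase Twinkle, had a log2 fold change of 1.51 ± 0.63 (SE), with overlapping groups, and of 1.03 without SUPV3L1 knockdown replicate 2. TBRG4, a FASTK family regulator of mitochondrial mRNA, was at 33.5 ± 12.9 CPM in PNPT1 knockdown and 54.2 ± 6.39 CPM in SUPV3L1 knockdown (SD, n = 3). PNPT1 and SUPV3L1 are themselves members of the list, with log2 fold changes of 0.97 and -0.70. No member passed, over all genes or adjusted over the list alone. Camera gave a Benjamini-Hochberg adjusted p of 0.0148 and, with an estimated correlation, an adjusted p of 0.689. The call was lost without PNPT1 knockdown replicate 1 (median 0.21), SUPV3L1 knockdown replicate 1 (median 0.24) or SUPV3L1 knockdown replicate 2 (median 0.22), and without PNPT1 knockdown replicate 2 the median was 0.45 and the log2 fold changes of C10orf2 and TBRG4 were 2.74 and 1.04, against 1.51 and 0.69.

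Replication-dependent histone mRNAs, which lack a poly(A) tail, were lower in SUPV3L1 knockdown in 48 of 49 members, with a median log2 fold change of -1.41 and 0 members past the threshold, over all genes or adjusted over the list alone. HIST1H1D was at 74.8, 54.0 and 552 CPM in PNPT1 knockdown and at 48.4, 21.2 and 20.5 CPM in SUPV3L1 knockdown. DESeq2, unlike edgeR, called HIST1H1D over all genes (Benjamini-Hochberg adjusted p = 0.0458). HIST1H2BF and HIST1H1C had log2 fold changes of -1.69 ± 0.48 and -2.02 ± 0.59 (SE). The mean log2 CPM of the histones was 5.49, 6.16 and 7.86 in PNPT1 knockdown and 5.86, 5.39 and 4.96 in SUPV3L1 knockdown. Cytosolic ribosomal protein mRNAs had log2 fold changes below 0 in 81 of 81 members (median -0.88), with 0 past the threshold, over all genes or adjusted over the list alone. RPS23 was at 759, 456 and 2207 CPM in PNPT1 knockdown and 509, 439 and 411 CPM in SUPV3L1 knockdown, and RPSA had a log2 fold change of -1.29 ± 0.56 (SE). Nuclear-encoded subunits of oxidative phosphorylation had 60 of 76 members below 0 (median -0.35), again with 0 past the threshold in either adjustment. NDUFS7, SDHA and ATP5I had log2 fold changes of -1.03 ± 0.44, -0.88 ± 0.44 and -1.05 ± 0.54 (SE). These 3 lists passed camera (Benjamini-Hochberg adjusted p = 2.53e-25, 1.10e-17 and 0.00243) and not with an estimated correlation (adjusted p = 0.620, 0.689 and 0.859). Without PNPT1 knockdown replicate 3, the median of the histones was -0.46, that of the ribosomal proteins was -0.10 and no longer past camera's threshold, and that of the oxidative phosphorylation subunits was 0.15, past camera's threshold in the other direction (Benjamini-Hochberg adjusted p = 0.00757). Without PNPT1 knockdown replicate 3, HIST1H1D, HIST1H2BF and HIST1H1C had log2 fold changes of -1.11, -0.94 and -0.91, RPS23 and RPSA of -0.43 and -0.36, and NDUFS7, SDHA and ATP5I of -0.40, -0.20 and -0.0469. The median of the oxidative phosphorylation subunits was -0.57 without PNPT1 knockdown replicate 2.

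Targets of ATF4 and the integrated stress response had 22 of 27 members below 0 and a median log2 fold change of -0.37, with none past the threshold, over all genes or adjusted over the list alone. PHGDH and SHMT2, enzymes of serine and one-carbon metabolism, were at 66.7 ± 24.2 and 94.3 ± 37.5 CPM in PNPT1 knockdown and at 34.7 ± 3.72 and 49.3 ± 3.86 CPM in SUPV3L1 knockdown (SD, n = 3). VLDLR, a lipoprotein receptor, was at 67.2 ± 13.3 against 33.6 ± 7.41 CPM (SD, n = 3). Camera gave a Benjamini-Hochberg adjusted p of 0.00715 and, with an estimated correlation, an adjusted p of 0.794. The call was lost without SUPV3L1 knockdown replicate 2 (median -0.18) and without PNPT1 knockdown replicate 2 (median 0.0354), and the median was -0.75 without PNPT1 knockdown replicate 1, whose mean log2 CPM over the list, 4.06, was the lowest of the 6 libraries.

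**Figure D3:**
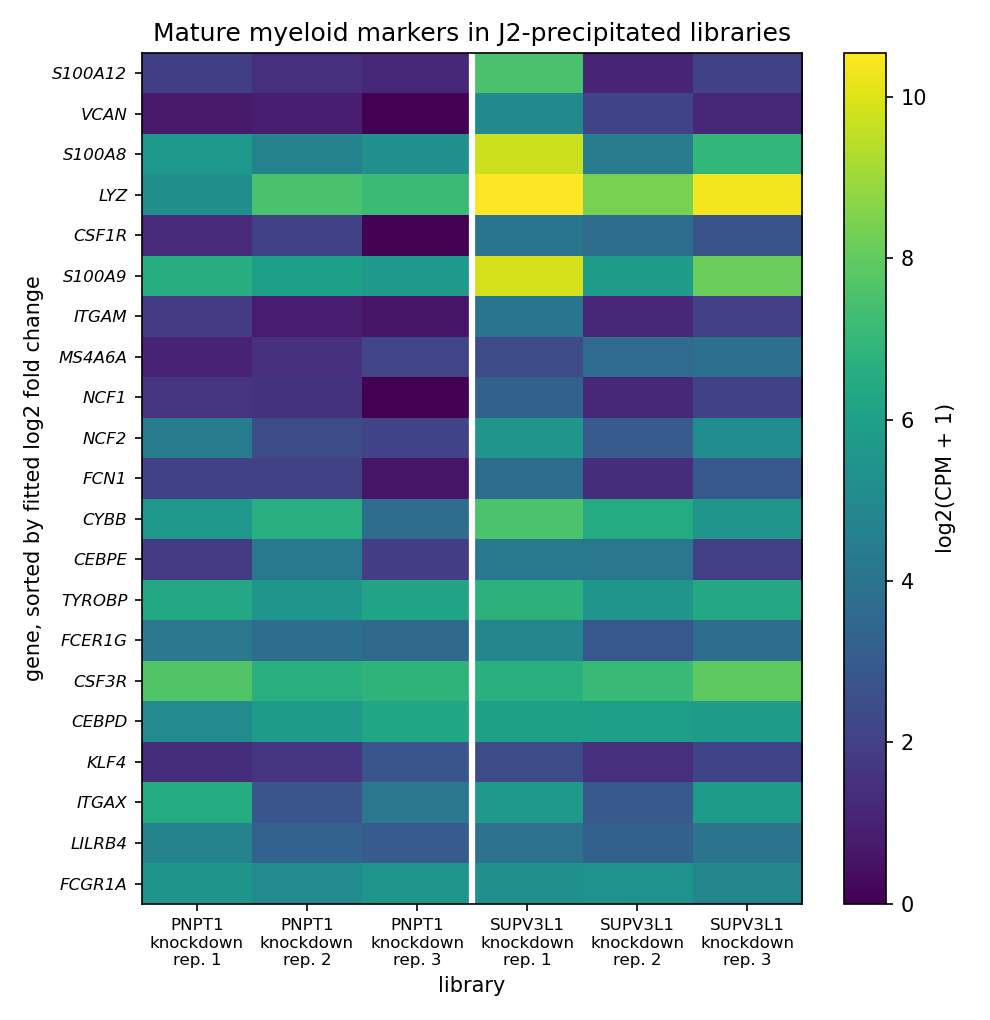
Levels of the 21 measured mature myeloid markers, as log2(CPM + 1) by colour, in each of the 6 libraries, sorted by fitted log2 fold change. LYZ, at 36.6 to 180 CPM in PNPT1 knockdown and 344 to 1493 CPM in SUPV3L1 knockdown, separates the groups, while the top member S100A12, at 183 CPM, is high in SUPV3L1 knockdown replicate 1 alone.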

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

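TMM scaling without the clone-named genes, the list tests under other scalings and filters, all settings of the mitochondrial rRNA share, and the ratio of mitochondrial rRNA to mRNA without 1 library were chosen after seeing the data. The count of 0 genes differing between the knockdowns held in edgeR under 4 other scalings and the strict filter, and in limma on FPKM under 3 settings. DESeq2 called 18 genes, and edgeR with no filter called 187, of which 145 were among the 13275 genes tested after the filter. Leaving out each library in turn gave 0 to 1 genes, the 1 being SERPINA1 without SUPV3L1 knockdown replicate 2. The cause was not tested in either case. The 9 lists past camera became 0 with an estimated correlation and 0 with fry, and 7 to 11 without each library. PNPT1 and SUPV3L1 kept their directions under every alternative run (log2 fold change 0.65 to 1.29 and -0.96 to -0.33). The mean mitochondrial share stayed higher in SUPV3L1 knockdown in every setting, by 3.99 percentage points without the mitochondrial rRNAs to 20.2 points without PNPT1 knockdown replicate 2, and the mean rRNA share by 8.08 (FPKM) to 17.5 points. Without the mitochondrial rRNAs the groups overlapped (exact permutation p = 0.4). The shares were then 7.11%, 7.67% and 2.04% in PNPT1 knockdown and 7.58%, 7.13% and 14.1% in SUPV3L1 knockdown. The difference in MT-ND6 share ranged from -1.95 to 2.30 percentage points without each library. Of the values of named genes, 901 were the same in direction and side of the threshold, 32 came past it and 11 turned sign. With each library left out, log2 fold changes ranged from -0.20 to 0.58 for MT-CYB, -0.89 to 0.79 for MT-ND5, -0.72 to 1.29 for MT-ND3, -0.13 to 1.04 for MT-ND4, -0.18 to 0.71 for MT-CO3, -0.0599 to 0.86 for MT-ATP8, -4.41 to 1.09 for HSPA1B, -3.97 to 0.32 for NR4A1, -3.86 to 1.26 for DUSP1 and -0.65 to 0.14 for MALAT1. List medians that turned sign without a library ranged from -1.26 to 1.34 (light-strand genes), -0.0281 to 0.27 (double-stranded RNA sensors), -0.16 to 0.24 (inverted Alu transcripts), -0.57 to 0.15 (oxidative phosphorylation), -0.21 to 0.17 (mitochondrial ribosome), -0.75 to 0.0354 (integrated stress response), -0.12 to 0.20 (p53 targets), -0.34 to 0.11 (cell cycle), -0.54 to 0.0206 (immune recognition), -0.56 to 0.29 (structured nuclear RNAs) and -1.44 to 0.81 (immediate early genes). With library size as the only scaling the medians of the mitochondrial ribosome and the cell cycle were 0.0838 and 0.0416, and with the strict filter that of the double-stranded RNA sensors was -0.0281. Scaled by library size only, histones, ribosomal proteins, oxidative phosphorylation subunits and immediate early genes had medians of -1.08, -0.60, -0.13 and -0.25. Their medians in the main test were -1.41, -0.88, -0.35 and -0.60. Those of interferon-stimulated genes and mitochondrial RNA machinery were 0.61 and 0.31, against 0.60 and 0.27, and 9 lists still passed camera. The causes were not tested. With no filter and on the log2(FPKM + 0.1) scale, the median over all genes was 0.11 in each, against 0.01 in the main test. No paired analysis was possible because the title numbers, whose meaning is unknown, differ between the groups and the replicate numbers follow accession order. In simulated counts 1 of 67 genes changed 2-fold was recovered, so changes of that size were mostly beyond these libraries. Recovery of larger changes may also be lower here than in the simulation, which drew genes independently.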

Other observations

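Of the tests below, those of both explanations for the mitochondrial rRNA share, the correlation of the myeloid list and its median without PNPT1 knockdown replicate 3, and the splits for genes past the adjusted threshold were chosen only after the result was seen. Several gene groups described here were measured outside the comparisons above. The 8 genes called by DESeq2 and not named above, chosen after their values were seen, were SERPINB2, LRRK2, OTOF, CLEC5A, HPSE, FGL2, TREM1 and FGR, with log2 fold changes of 4.35, 3.80, 3.70, 3.29, 3.17, 3.10, 2.64 and 1.99 in SUPV3L1 minus PNPT1 knockdown (adjusted p from 0.00867 to 0.0458 by DESeq2 with Benjamini-Hochberg adjustment, and 0.898 for each by edgeR's quasi-likelihood test). SERPINA1 had 6, 9 and 1 counts in PNPT1 knockdown and 399, 5 and 254 in SUPV3L1 knockdown. Markers of other cell types were near the floor for most members: 2 of 15 erythroid, 3 of 22 lymphoid and 3 of 20 epithelial or fibroblast genes passed the filter, and the mean log2 CPM of those measured was 5.18 ± 0.56, 2.96 ± 0.27 and 0.92 ± 0.52 in PNPT1 knockdown and 4.96 ± 0.37, 2.83 ± 0.12 and 1.55 ± 0.60 in SUPV3L1 knockdown (SD, n = 3).

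Lists without a camera call (Benjamini-Hochberg adjusted p from 0.151 to 0.961) included the immediate early and heat shock genes, whose median log2 fold change was -0.60. HSPA1B was at 142 CPM in PNPT1 knockdown replicate 3 and at 1.19 to 4.77 CPM in the other 5 libraries, DUSP1 at 90.6 against 1.04 to 4.36 CPM, and NR4A1 at 49.9 against 0.660 to 2.38 CPM. The medians of the other lists were 0.17 for transcripts with inverted Alu repeats and 0.06 for p53 targets, where camera's direction was downward, -0.06 for mitochondrial ribosomal proteins, -0.06 for cell cycle genes and -0.29 for structured nuclear RNAs. The immediate early and heat shock list passed camera downward without PNPT1 knockdown replicate 1 (median -0.94, Benjamini-Hochberg adjusted p = 6.83e-05), PNPT1 knockdown replicate 2 (-0.92, adjusted p = 0.0175) or SUPV3L1 knockdown replicate 1 (-1.44, adjusted p = 7.43e-04), and upward without PNPT1 knockdown replicate 3. Without PNPT1 knockdown replicate 3, the medians were 0.81 for immediate early and heat shock genes (camera, Benjamini-Hochberg adjusted p = 2.84e-06), 0.29 for structured nuclear RNAs (adjusted p = 0.0228), 0.17 for mitochondrial ribosomal proteins (adjusted p = 0.0210) and -0.16 for transcripts with inverted Alu repeats. The median was -0.12 for p53 targets without SUPV3L1 knockdown replicate 2 and 0.11 for cell cycle genes without SUPV3L1 knockdown replicate 3. Camera called mitochondrial ribosomal proteins downward without PNPT1 knockdown replicate 1 (median -0.21, Benjamini-Hochberg adjusted p = 0.0234), and cell cycle genes without PNPT1 knockdown replicate 1 (-0.34, adjusted p = 0.00509) or SUPV3L1 knockdown replicate 1 (-0.18, adjusted p = 0.0147). Camera calls without a library, here and above, used the preset correlation. At that setting camera passed 5 to 13 lists in every split of the libraries described below, so these calls carry little weight. With all libraries and an estimated correlation, no list passed (smallest Benjamini-Hochberg adjusted p = 0.620).

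PNPT1 knockdown replicate 3 detected 16620 genes. When the other 5 libraries were thinned to its assigned count they still detected 19587 or more, which argues against depth as the whole cause. With clone-named and mitochondrial genes removed and all libraries thinned to one total, the others detected 19176 or more against its 16566, which argues against a few genes taking the counts. The 500 protein-coding genes most abundant in the other libraries took 45.8% of its nuclear protein-coding counts against at most 35.9% elsewhere, a tilt toward abundant mRNAs. A larger share on abundant genes leaves fewer counts for the others, so this tilt largely restates the pattern and cannot single out a cause. Whether the tilt came from the cells, through the stress genes above, or from the precipitation was not tested.

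The mitochondrial rRNA share was higher in SUPV3L1 knockdown. If the clone-named genes had only diluted it in PNPT1 knockdown, leaving them out of the total would bring the groups together, but the lowest SUPV3L1 library was still 1.24 times the highest PNPT1 library. The ratio of rRNA to mRNA counts overlapped between the groups, with the lowest SUPV3L1 library at 0.667 times the highest PNPT1 library, but the overlap rests on PNPT1 knockdown replicate 3 (5.12): without it the PNPT1 ratios were 2.62 and 3.37 against 5.41, 5.61 and 3.42, and the value was 1.02. Whether the difference is common to mitochondrial rRNA and mRNA therefore stays open. A difference in the effect of the knockdowns on mitochondrial RNA, in the precipitation or in the extent of the knockdown stays open, and with no control library none of them was tested.

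The mature myeloid list was higher in SUPV3L1 knockdown. Its median exceeded 100% of random lists matched on expression, which argues against the expression level of its members as the cause, and without PNPT1 knockdown replicate 3 the median was 1.13. Without SUPV3L1 knockdown replicate 1 it was 0.51, under a median of 1.52 with all libraries, so that library may carry much of the size. Camera's Benjamini-Hochberg adjusted p remained at 1.09e-04 without it. At the preset correlation, however, camera passed 5 to 13 lists in every split of the libraries described below, so this p does not weigh against that explanation. With an estimated correlation camera gave an unadjusted p of 0.0530 (Benjamini-Hochberg adjusted p = 0.620), so members that vary together between libraries may account for the strength of the preset test.

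The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past edgeR's adjusted threshold the comparison carries no information, because the real split gave 0 and every one of the 10 splits must give at least as many. At an unadjusted p under 0.05 the real split gave 543 genes and the highest other 2000, with 4 of 10 splits giving as many. That split set PNPT1 knockdown replicates 1 and 3 and SUPV3L1 knockdown replicate 3 against the rest. A count several times the real one points to a structure of the samples that crosses the knockdowns, although 0 genes passed the adjusted threshold in that split. The highest correlations across genes also joined libraries on the same side of that split. Pearson's r was 0.970 for PNPT1 and SUPV3L1 knockdown replicates 2 and 0.946 for PNPT1 knockdown replicate 1 and SUPV3L1 knockdown replicate 3. Within a group it was at most 0.943. The cause of this structure was not tested. For lists past camera the real split gave 9 and the highest other 13, with 9 of 10 giving as many, and for the myeloid list the real p was 3.89e-09 and the smallest other 1.63e-11, with 2 of 10 giving as small a p. The smallest came from PNPT1 knockdown replicate 1 and SUPV3L1 knockdown replicates 1 and 3 against the rest (median -1.13, the rest minus these). By camera's p, the myeloid list thus separated this mixed grouping more strongly than it separated the knockdowns. Its median, however, was largest in size in the real split, at 1.52. With 10 splits, neither ranking can decide whether the list follows the knockdowns.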
